A study of Mus musculus with 15 samples.

How the data were processed

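Gene expression was measured on 15 microarrays of bone marrow cells from mice, in 5 groups of 3 arrays. Per the labels' protocols and the series text, marrow of female C57Bl/6 donors given 5-fluorouracil was transduced with a retroviral vector carrying HOXB4 and a yellow fluorescent protein, or with a vector carrying green fluorescent protein (GFP) alone, and transplanted into lethally irradiated mice. Fluorescent LSK cells, the lineage-negative Sca-1+ Kit+ fraction that holds blood stem cells and early progenitors, were later sorted. Per the labels' protocols, the cells were not cultured, RNA was extracted with the RNAqueous-Micro kit, and 20 ng of total RNA were amplified to biotin-labelled cDNA with NuGEN reagents. The sample titles give times of 6, 12 and 20 weeks after transplantation, whereas the series text gives 24 weeks as the last time. The times of the titles were used. A GFP group at 6 weeks was not analysed here.

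The values used are the authors' deposited log2 expression values, 1 table of 45141 probe sets on 15 arrays, which came from RMA in Partek 6.5, per the submitters' processing notes. RMA corrects the background, quantile-normalises the arrays and summarises probes to probe sets. Which probes were filtered, and whether further scaling was applied, is not given in the sources used here. No detection calls were used, so the number of arrays limits the precision, and a low value may be background. The median of the log2 values lay between 5.247 and 5.397 on the 15 arrays.

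Probe sets were named through the platform annotation, with symbols updated through the gene identifier against the GRCm38.p6 gene table. Of the probe sets, 28898 had 1 gene symbol, 551 had several and were not named, and 15692 were not listed in that annotation. Of those with 1 symbol, 28689 were matched through the gene identifier and 209 kept the symbol of the annotation. For each of the 17097 genes the probe set with the highest mean over the 15 arrays was tested. More than 1 probe set was present for 7180 genes. Where another probe set of a named gene was available it was checked for a call in the opposite direction. GRCm38.p6 served for symbols, for the chromosome of a gene and, through the start positions of genes, for which genes neighbour each other.

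All 15 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 10 residual and 4.55 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the 17097 genes, and a gene was called at an adjusted p under 0.05. The comparisons were HOXB4 against GFP at 12 weeks, at 20 weeks and as the mean of both times, the difference between the effects at both times, HOXB4 at 12 against 6, 20 against 12 and 20 against 6 weeks, and GFP at 20 against 12 weeks. Values are log2 differences with the standard error of the model, or group means with the standard deviation (SD). With 3 arrays against 3, an exact two-sided permutation test of a single gene cannot go below 0.1, so the adjusted p-values rest on the model. The labels do not say that the 3 arrays of a group came from different mice, so p-values measure only the spread between these arrays, which may be technical.

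A set of 45 gene lists was tested in all 8 comparisons, 33 of pathways or progenitor classes and 12 of markers of other cells that the sort could hold. The test was limma's camera with a preset correlation of 0.01, adjusted over all 360 tests, of which 122 passed. With a correlation estimated for each list, 2 of the 122 passed, both for mature neutrophil markers. The alternative fry asks whether the genes of a list move one way on balance, without comparing them with other genes. With fry 73 of the 360 tests passed, among them 61 of the 122. Members of a list were counted over all genes and adjusted over the list alone.

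The genes named are the 12 with the largest rise and the 12 with the largest fall among called genes for each HOXB4 against GFP comparison, and 5 in each direction for each other comparison. Symbols of predicted genes, of olfactory and vomeronasal receptors and of small RNAs were left out of this ranking but not of counts. Prdm16, Hemgn, Mecom, Meis1, Hoxa9 and Hoxb4 were always reported, and up to 4 members of a list with the smallest p could be named. The rule named 70 genes by size of change. A further probe set was available for 28 of them, and 0 of the 70 had another probe set called the opposite way. For 10 the tested probe set carries a name that marks possible cross-hybridisation.

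The groups, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were a fit on only the groups compared, a filter removing the dimmest 1 in 3 genes by mean signal, all probe sets, the mean of a gene's probe sets, quantile normalisation, centring of each array on its median, a variance trend with robust moderation, no moderation, array weights, the replicate number as a block, and leaving out each array in turn. A covariate for RNA quality (the 3' minus 5' signal of the Gapdh controls) and a fit without the array of each 20-week group with the highest Dap control signal were added after seeing the data. The model was tested on simulated data for 17097 genes with each gene's pooled spread between these arrays, taken as the same in all groups. For HOXB4 against GFP at 12 weeks it recovered 81 of 100 genes with a true log2 change of 1 and 100 of 100 with a change of 2, with 9 false calls. In a simulated comparison at 20 weeks with no change it made 0 calls.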

Results

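LSK cells, the bone marrow fraction that holds blood stem cells and early progenitors, were compared between mice transplanted with marrow carrying a HOXB4 vector and mice transplanted with marrow carrying a GFP vector. HOXB4 is a homeobox transcription factor whose forced expression expands blood stem cells. HOXB4 cells were profiled at 6, 12 and 20 weeks after transplantation and GFP cells at 12 and 20 weeks, with 3 arrays in each of the 5 groups. The values are log2 RMA signals, and differences are given on the log2 scale with the standard error of the model.

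At 12 weeks, replicate arrays correlated with each other between 0.990 and 0.994 in HOXB4 and between 0.991 and 0.992 in GFP cells. The range was 0.978 to 0.983 in HOXB4 and 0.981 to 0.992 in GFP cells at 20 weeks, and 0.967 to 0.979 in HOXB4 cells at 6 weeks. Arrays of different groups correlated between 0.948 and 0.987. The median SD of a gene between replicates was 0.114 in HOXB4 and 0.128 in GFP cells at 12 weeks, 0.176 and 0.145 at 20 weeks, and 0.203 in HOXB4 cells at 6 weeks. Replicate 1 of the 6-week HOXB4 group had a 3' minus 5' signal of the Gapdh controls of 3.764, against 0.809 to 2.016 on the other 14 arrays. The Dap control, a spiked-in bacterial RNA, was brightest on replicate 3 of GFP at 20 weeks (12.63) and replicate 3 of HOXB4 at 20 weeks (11.82).

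Prdm16, a transcription factor required by blood stem cells, was 1 of 6 genes reported whatever their change, all linked to HOXB4 or to stem cell self-renewal. Its tested probe set was at 5.92 ± 0.06 in GFP and 5.78 ± 0.13 in HOXB4 cells at 12 weeks, and at 7.23 ± 0.48 in GFP and 5.83 ± 0.19 in HOXB4 cells at 20 weeks (SD, n = 3). Prdm16 was thus lower in HOXB4 than in GFP cells at 20 weeks by a log2 change of -1.40 ± 0.19 (2.63-fold; adjusted p = 0.000274), and did not pass at 12 weeks (-0.13 ± 0.19, adjusted p = 0.758). Between 12 and 20 weeks it rose in GFP cells by 1.31 ± 0.19 (adjusted p = 0.00164) and differed by 0.05 ± 0.19 in HOXB4 cells (adjusted p = 0.953). The difference between the effects at both times was -1.26 ± 0.26 and narrowly missed the threshold (adjusted p = 0.0505). All 4 probe sets of Prdm16 moved alike. HOXB4 against GFP at 20 weeks gave -1.40, -2.57, -3.30 and -4.17, and GFP at 20 against 12 weeks gave 1.31, 2.28, 3.50 and 3.68. The 3 other probe sets each passed the test of the difference between times when all named probe sets were tested (adjusted p = 0.0465, 0.0275 and 0.00567).

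Hemgn, an erythroid nuclear protein known as a HOXB4 target, was higher in HOXB4 than in GFP cells at 20 weeks by 1.57 ± 0.22 (2.98-fold; adjusted p = 0.000368). The difference at 12 weeks was 0.66 ± 0.22 (adjusted p = 0.108), and the difference between both effects was 0.91 (adjusted p = 0.269). Over both times Hemgn was higher by 1.12 ± 0.15 (adjusted p = 0.000271). In GFP cells it fell by 1.36 between 12 and 20 weeks (adjusted p = 0.00389). Hoxa9 was higher in HOXB4 cells at 20 weeks by 0.80 ± 0.18 (adjusted p = 0.0112) and fell by 1.25 in GFP cells between 12 and 20 weeks (adjusted p = 0.00179). Its difference between vectors at 12 weeks was -0.09 ± 0.18 (adjusted p = 0.838), and the difference between both effects was 0.89 (adjusted p = 0.175). Meis1, the partner of Hox proteins, differed at 20 weeks by 0.92 ± 0.32 (adjusted p = 0.0975) on the tested probe set and by 1.17 ± 0.30 on the other (adjusted p = 0.0236 over all named probe sets). Mecom, a relative of Prdm16, passed in none of the comparisons, with 0.27 ± 0.10 between vectors at 20 weeks (adjusted p = 0.112). The tested probe set of mouse Hoxb4 passed in none of the comparisons, with -0.30 ± 0.24 at 12 and -0.15 ± 0.24 at 20 weeks (adjusted p = 0.528 and 0.782). The other probe set gave -0.59 ± 0.17 at 12 and -0.08 ± 0.17 at 20 weeks (adjusted p = 0.0727 and 0.853 over all named probe sets). Whether either lies in the part of HOXB4 that the vector carries is not given in the sources used here, so they check nothing about the labels. Neither Prdm16, Hemgn, Hoxa9, Meis1, Mecom nor Hoxb4 passed between any of the 3 times in HOXB4 cells.

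**Figure D1:**
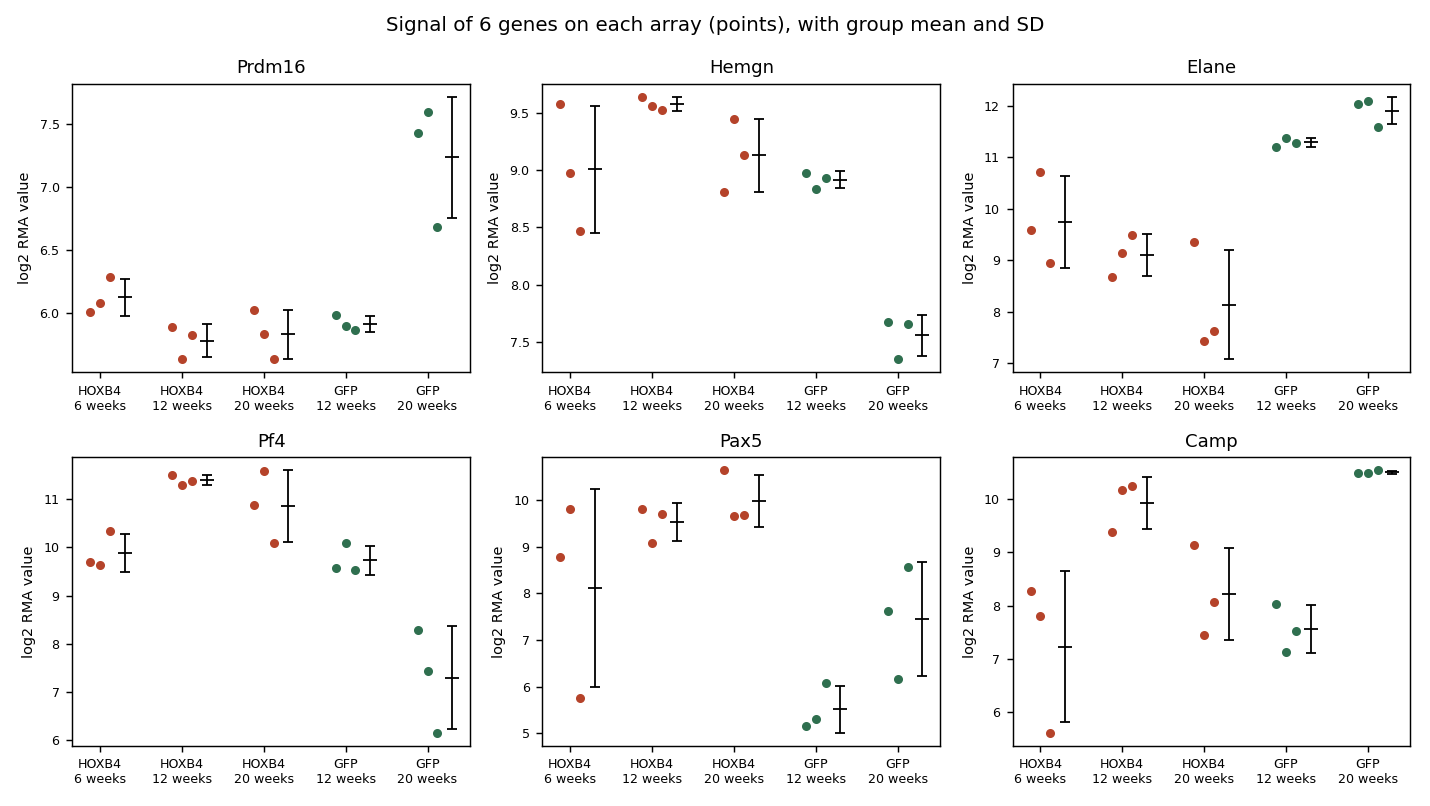
Log2 RMA signal of Prdm16, Hemgn, Elane, Pf4, Pax5 and Camp on each array (points, red for HOXB4 and green for GFP), with the group mean and SD of 3 arrays in black. Prdm16 lies between 6.69 and 7.59 on the GFP arrays at 20 weeks and between 5.64 and 6.29 on all others, and Camp lies between 10.49 and 10.54 on the GFP arrays at 20 weeks.

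At 12 weeks, 14 gene lists differed between HOXB4 and GFP cells by the list test with a preset correlation, 7 higher and 7 lower in HOXB4 cells, and none of them with an estimated correlation. Pax5 (4.01 ± 0.79; 16.1-fold) and Ebf1 (3.70 ± 0.72), which commit progenitors to the B lineage, were higher, as were the recombinase Rag1 (3.83 ± 0.72) and the surrogate light chains Vpreb1 (3.75 ± 0.79) and Vpreb2 (3.39 ± 0.64). So were the heavy chain Ighm (3.42 ± 0.39) and its signalling partner Cd79a (3.33 ± 0.68). The neutrophil elastase Elane (-2.18 ± 0.45; 4.54-fold), the related protease Prtn3 (-1.92 ± 0.41) and Ms4a3 (-1.92 ± 0.33), all genes of granulocyte progenitors, were lower. The eosinophil granule genes Epx (-2.75 ± 0.66) and Prg3 (-2.31 ± 0.58) were lower as well. Other genes with the largest rises were Mup3, which encodes a urinary protein made mainly by liver (4.03 ± 0.40), the sialyltransferase St3gal6 (3.69 ± 0.52), Gfra2 (3.54 ± 0.62), Sdc4 (3.49 ± 0.60) and Lilrb4a (3.02 ± 0.41). Other large falls were those of the junction genes Tjp1 (-2.87 ± 0.32) and Gja1 (-2.26 ± 0.34), Tmem98 (-2.33 ± 0.41), Tnfsf13 (-2.04 ± 0.38), B4galt6 (-1.97 ± 0.27), Mc5r (-1.87 ± 0.26) and Col4a2 (-1.85 ± 0.31). The adjusted p of these 24 genes lay between 0.000484 and 0.0379. The mean of its probe sets gave 1.53 for St3gal6. For each of these 24 genes all 3 HOXB4 arrays lay on 1 side of all 3 GFP arrays, as for all 688 called genes. The genes were chosen on these same arrays, so this separation is no further support. By chance it happens for 10% of unchanged genes.

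Among the gene lists at 12 weeks, 9 of the 19 measured genes of granulocyte-monocyte progenitors were lower and 10 were not called, and 14 were lower adjusted over the list alone. The median was -0.99 (adjusted p = 1.2e-11, and adjusted p = 0.23 with an estimated correlation). They included Ctsg (-1.79), Cebpa (-1.53) and the receptor Csf3r (-1.53). Of 15 lymphoid priming genes, 4 were higher, 0 lower and 11 not called, with 7 higher adjusted over the list alone. Their median was 0.59 (adjusted p = 6.3e-07, and adjusted p = 0.28 with an estimated correlation). Of 13 B cell markers, 6 were higher and 7 not called, with 7 higher adjusted over the list alone. Their median was 1.27 (adjusted p = 9.3e-08, and adjusted p = 0.30 with an estimated correlation). Pax5, Ighm, Vpreb3 (2.62) and Cd72 (1.27) were among them. Mature neutrophil markers had a median of 1.15, with 1 of 13 higher, the antimicrobial peptide Camp (2.37), and 12 not called. Adjusted over the list alone 6 were higher and 1 lower (adjusted p = 0.00063, and adjusted p = 0.28 with an estimated correlation). Of 6 eosinophil markers 2 were lower and 4 not called, with 4 lower adjusted over the list alone. The median was -1.47 (adjusted p = 0.039, and adjusted p = 0.44 with an estimated correlation).

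Several lists of cell state also passed at 12 weeks. Of 23 immediate-early genes, 7 were higher, among them Jun (2.43) and Jund (1.36), and 16 were not called, with 10 higher and 1 lower adjusted over the list alone. Their median was 0.58 (adjusted p = 0.00014, and adjusted p = 0.51 with an estimated correlation). Of 28 glycolysis and hypoxia genes, 7 were lower, including Egln3 (-1.36), Pfkp (-0.66) and Aldoa (-0.60), 1 was higher, Ddit4 (1.31), and 20 were not called, with 10 lower and 1 higher adjusted over the list alone. Their median was -0.28 (adjusted p = 0.00029, and adjusted p = 0.23 with an estimated correlation). Of 22 unfolded protein response genes, 4 were lower, led by Sdf2l1 (-0.88) and Pdia4 (-0.85), and 18 not called, with 9 lower adjusted over the list alone. The median was -0.37 (adjusted p = 0.0015, and adjusted p = 0.41 with an estimated correlation). Of 24 cytokine receptors, 5 were lower, including Il6ra (-1.30) and Kit (-0.63), and 19 not called, with 6 lower adjusted over the list alone. Their median was -0.22 (adjusted p = 0.0021, and adjusted p = 0.14 with an estimated correlation). Of 17 megakaryocyte genes, 4 were higher, including Pf4 (1.67) and Treml1 (1.44), and 13 not called, with 4 higher adjusted over the list alone. Their median was 0.24 (adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation).

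In all, 688 genes were called at 12 weeks, 312 higher and 376 lower in HOXB4 cells, of which 139 and 73 changed at least 2-fold. The larger share changed with the processing, with 267 higher and 227 lower after a further quantile normalisation, 830 and 627 over all probe sets, and 282 and 490 with each array centred on its median. A fit on these 2 groups alone, which had the smallest spread between replicates, called 2593 genes, and array weights gave 2791 and no moderation 308. The count moved by over 1.5 times when 1 array of the comparison was left out, to 214, 362 and 223 without GFP replicates 1, 2 and 3 and to 234, 244 and 309 without HOXB4 replicates 1, 2 and 3. In each of these 6 fits more genes were higher than lower.

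At 20 weeks, 17 gene lists differed by the list test with a preset correlation, 9 higher and 8 lower in HOXB4 cells, and none of them with an estimated correlation. The neutrophil granule gene Lcn2 (-4.19 ± 0.64) was lower, and so were Chil3 (-4.57 ± 0.56; 23.7-fold) and Chil4 (-4.36 ± 0.31), which encode chitinase-like proteins of myeloid cells. Pglyrp1 (-3.65 ± 0.29), Elane (-3.77 ± 0.45) and Prtn3 (-3.81 ± 0.41), genes of granulocytic cells, were lower as well. So were the coagulation factor F13a1 (-4.35 ± 0.47), the receptor gene Mrgpra2b (-4.86 ± 0.32), the gluconeogenic enzyme Fbp1 (-4.37 ± 0.34), the sphingomyelin synthase Sgms2 (-4.01 ± 0.39), Mtus1 (-3.96 ± 0.29) and Nudt6 (-3.95 ± 0.33). The platelet chemokine Pf4 (3.56 ± 0.43; 11.8-fold), St3gal6 (3.81 ± 0.52), the chloride channel regulators Clca3a2 (3.66 ± 0.61) and Clca3a1 (3.43 ± 0.69), the Fc receptor chain Ms4a2 (3.45 ± 0.41) and Mab21l2 (3.35 ± 0.67) were higher. The other largest rises were those of the T cell receptor segment Trbv13-2 (3.23 ± 0.35), the interferon-induced GTPase Iigp1 (3.23 ± 0.52), Gnb4 (3.03 ± 0.25), the sphingosine 1-phosphate exporter Mfsd2b (2.94 ± 0.33), Gfra2 (2.88 ± 0.62) and Arhgap6 (2.84 ± 0.39). The adjusted p of these 24 genes lay between 1.97e-06 and 0.00861. The arrays of both groups did not overlap for any of them, nor for 1491 of the 1530 called genes. With the mean of a gene's probe sets in place of the brightest, St3gal6 was at 1.99, Clca3a2 at 1.29, Clca3a1 at 2.12 and Chil4 at -2.18, all still called. Clca3a1 was at 2.26 without HOXB4 replicate 2 at 20 weeks. The other probe sets of Clca3a2 (0.13 and 0.08), Clca3a1 (0.82) and Chil4 (0.01) were not called.

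Of the 19 granulocyte-monocyte progenitor genes, 17 were lower at 20 weeks and 2 not called, with 17 lower and 1 higher adjusted over the list alone. The median was -1.70 (adjusted p = 4.6e-21, and adjusted p = 0.14 with an estimated correlation). The transcription factor Cebpa (-2.69), Ctsg (-2.97) and Ms4a3 (-3.40) were among them. Markers of mature neutrophils moved with them, with 11 of 13 lower, 2 not called, and 11 lower adjusted over the list alone. Their median was -2.65 (adjusted p = 2.8e-11, and adjusted p = 0.14 with an estimated correlation), and Ltf (-2.73) and Cd177 (-2.68) were among them. Of 17 monocyte and macrophage markers, 5 were lower, among them Lyz2 (-2.07), Cd68 (-2.10) and Csf1r (-1.87), and 12 not called, with 7 lower and 1 higher adjusted over the list alone. Their median was -0.49 (adjusted p = 1.1e-05, and adjusted p = 0.14 with an estimated correlation). Of 6 eosinophil markers, 3 were lower and 3 not called, with 3 lower adjusted over the list alone. The median was -1.56 (adjusted p = 0.0029, and adjusted p = 0.26 with an estimated correlation). Of 17 megakaryocyte genes, 10 were higher, including the integrin Itga2b (1.66) and Rab27b (2.35), and 7 not called, with 12 higher adjusted over the list alone. Their median was 1.20 (adjusted p = 1.6e-07, and adjusted p = 0.27 with an estimated correlation). Of 15 lymphoid priming genes, 8 were higher, including Dntt (2.27), Rag2 (2.46) and Satb1 (1.28), and 7 not called, with 12 higher adjusted over the list alone. Their median was 1.28 (adjusted p = 3.2e-07, and adjusted p = 0.28 with an estimated correlation). The B cell markers did not pass at 20 weeks, with 2 of 13 higher, 11 not called and 3 higher adjusted over the list alone. The median was 0.21 (adjusted p = 0.30, and adjusted p = 0.82 with an estimated correlation). The difference between the effects at 20 and 12 weeks had a median of -0.95 over these markers, with 1 of 13 called lower, Ighm, 12 not called, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.00055, and adjusted p = 0.53 with an estimated correlation).

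Signalling and metabolic lists passed at 20 weeks as well. Of 28 TGF-beta and BMP signalling genes, 9 were higher, including Smad1 (2.36) and Smad7 (1.17), 2 lower, including Id1 (-0.92), and 17 not called, with the same counts adjusted over the list alone. Their median was 0.21 (adjusted p = 0.03, and adjusted p = 0.23 with an estimated correlation). Of 35 interferon response genes, 7 were higher, including Rtp4 (1.68) and Gbp2 (1.41), 1 lower and 27 not called, with 9 higher and 1 lower adjusted over the list alone. Their median was 0.30 (adjusted p = 5e-04, and adjusted p = 0.51 with an estimated correlation). Of 12 HoxA cluster and cofactor genes, 1 was higher, Hoxa9, and 11 not called, also adjusted over the list alone. The median was 0.38 (adjusted p = 0.022, and adjusted p = 0.23 with an estimated correlation). Of 27 antioxidant genes, 8 were lower, including the glutathione reductase Gsr (-2.57), Gstm1 (-2.24) and Gclm (-1.09), and 19 not called, with 10 lower adjusted over the list alone. Their median was -0.13 (adjusted p = 0.0011, and adjusted p = 0.41 with an estimated correlation). Of 22 unfolded protein response genes, 10 were lower, including Edem1 (-0.78) and Sel1l (-0.82), and 12 not called, with 14 lower and 1 higher adjusted over the list alone. Their median was -0.50 (adjusted p = 1.9e-08, and adjusted p = 0.23 with an estimated correlation). Of 28 glycolysis and hypoxia genes, 9 were lower, including Ldhb (-2.62) and Egln3 (-2.02), and 19 not called, with 10 lower and 1 higher adjusted over the list alone. The median was -0.17 (adjusted p = 0.00051, and adjusted p = 0.23 with an estimated correlation).

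At 20 weeks 1530 genes were called, 645 higher and 885 lower in HOXB4 cells, of which 235 and 314 changed at least 2-fold. A fit on these 2 groups alone called 715 genes. Without GFP replicate 1 the count was 887, and without GFP replicate 2 it was 798.

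**Figure D2:**
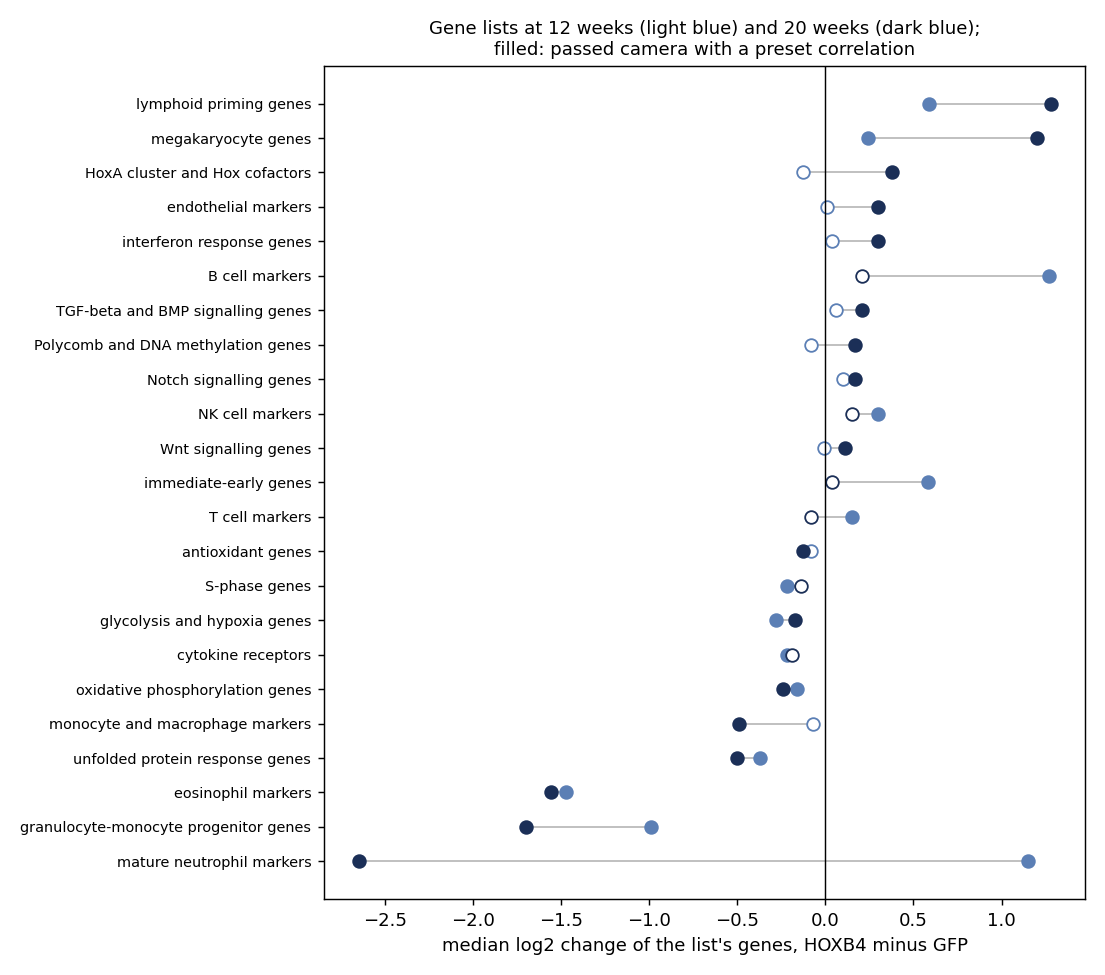
Median log2 difference between HOXB4 and GFP cells over the measured genes of each list that passed at either time (horizontal axis), at 12 weeks (light blue) and 20 weeks (dark blue), with filled points for lists that passed camera with the preset correlation. The mature neutrophil markers lie at 1.15 at 12 weeks and at -2.65 at 20 weeks.

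Over both times together, the lists of granulocyte-monocyte progenitor genes and eosinophil markers were lower in HOXB4 cells by the list test, and those of lymphoid priming, B cell and megakaryocyte genes higher. None of these calls held with an estimated correlation (adjusted p = 0.14, 0.28, 0.24, 0.53 and 0.33). St3gal6 (3.75 ± 0.37; 13.5-fold), Pax5 (3.28 ± 0.56), Gfra2 (3.21 ± 0.44), Sdc4 (3.16 ± 0.43), Rag1 (3.13 ± 0.51), Vpreb1 (3.07 ± 0.56), Ebf1 (3.02 ± 0.51), Clca3a2 (3.0 ± 0.43), Vpreb2 (2.93 ± 0.45), Clca3a1 (2.80 ± 0.49), Trbv13-2 (2.75 ± 0.25) and Ms4a2 (2.74 ± 0.29) showed the largest rises. Mrgpra2b (-3.23 ± 0.22; 9.40-fold), Fbp1 (-2.99 ± 0.24), Elane (-2.98 ± 0.32), Prtn3 (-2.87 ± 0.29), the eosinophil genes Ear3 (-2.82 ± 0.77), Epx (-2.82 ± 0.47) and Prg2 (-2.77 ± 0.63), Sgms2 (-2.74 ± 0.28), F13a1 (-2.72 ± 0.33), Ms4a3 (-2.66 ± 0.23), Tnfsf13 (-2.58 ± 0.27) and Tjp1 (-2.56 ± 0.23) showed the largest falls. The adjusted p of these 24 genes lay between 3.05e-06 and 0.0233. Of them 22 separated the arrays of both vectors at each time, as did 1558 of the 2625 called genes. The mean of a gene's probe sets gave 1.76 for St3gal6, 1.08 for Clca3a2 and 1.79 for Clca3a1.

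Of the 19 granulocyte-monocyte progenitor genes, 17 were lower over both times, 1 higher and 1 not called, with 18 lower and 1 higher adjusted over the list alone. Their median was -1.34 (adjusted p = 4e-18, and adjusted p = 0.14 with an estimated correlation). Of 15 lymphoid priming genes, 10 were higher and 5 not called, with 13 higher adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.24 with an estimated correlation). Of 17 megakaryocyte genes, 11 were higher and 6 not called, with 11 higher adjusted over the list alone. Their median was 0.75 (adjusted p = 8.7e-06, and adjusted p = 0.33 with an estimated correlation). Of 13 B cell markers, 7 were higher and 6 not called, with 7 higher adjusted over the list alone. Their median was 0.98 (adjusted p = 0.00066, and adjusted p = 0.53 with an estimated correlation). Of 6 eosinophil markers, 4 were lower and 2 not called, with 4 lower adjusted over the list alone. Their median was -1.51 (adjusted p = 0.0054, and adjusted p = 0.28 with an estimated correlation). Of 67 oxidative phosphorylation genes, 10 were lower and 57 not called, with 12 lower adjusted over the list alone. Their median was -0.22 (adjusted p = 4e-07, and adjusted p = 0.53 with an estimated correlation). In all, 2625 genes were called, 1059 higher and 1566 lower, and with each array centred on its median 810 were higher and 1936 lower. The comparisons at 12 and at 20 weeks share no arrays. Both use the same estimate of each gene's spread, which favours the same genes, so their calls are not independent. Both comparisons shared 101 genes called higher, where independent lists would share 11.8, and 194 called lower, where independent lists would share 19.5. Across genes, which are not independent replicates, the changes at both times correlated with a Pearson r of 0.55 and a Spearman rho of 0.50. Camp, Cd200r4, Chil4, Fadd and Hmga2, 5 genes named after their values were seen, were called in opposite directions at both times.

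The effect of HOXB4 differed between 20 and 12 weeks above all in genes of mature neutrophils, which had a median of 1.15 in HOXB4 against GFP cells at 12 weeks and of -2.65 at 20 weeks. The difference between effects was -6.40 ± 0.79 for Chil3 (adjusted p = 0.00176), -6.07 ± 0.43 for Chil4 (adjusted p = 1.25e-05), -5.55 ± 0.90 for Lcn2 (adjusted p = 0.00995), -4.66 ± 0.78 for Camp (adjusted p = 0.0122) and -4.0 ± 0.44 for Fcnb, a ficolin of myeloid cells (adjusted p = 0.000733). It was positive for Stxbp4 (2.43 ± 0.35, adjusted p = 0.00426), Tmprss3 (1.98 ± 0.36, adjusted p = 0.0239), the prostaglandin receptor Ptger3 (1.82 ± 0.38, adjusted p = 0.0498), the chromatin protein gene Hmga2 (1.64 ± 0.29, adjusted p = 0.0181) and the cytokine Il18 (1.59 ± 0.32, adjusted p = 0.0378). Averaged over their probe sets, Chil4 was at -3.20 and Stxbp4 at 1.51, both still called. Ptger3 lost its call in 16 of 27 alternatives, Tmprss3 in 9 of 27 and Il18 in 11 of 26. Of 13 mature neutrophil markers, 5 were called lower and 8 not called, with 11 lower adjusted over the list alone. The median was -3.89 (adjusted p = 1.3e-21, and adjusted p = 0.046 with an estimated correlation). Of 17 monocyte and macrophage markers, 2 were lower, Lyz2 (-2.42) and F13a1 (-3.25), and 15 not called, with 4 lower adjusted over the list alone. Their median was -0.27 (adjusted p = 0.00011, and adjusted p = 0.20 with an estimated correlation). The granulocyte-monocyte progenitor genes had 0 of 19 called and 10 lower adjusted over the list alone. Their median was -0.71 (adjusted p = 1.2e-08, and adjusted p = 0.24 with an estimated correlation).

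In all, the effects differed for 87 genes, 21 with a positive and 66 with a negative difference. The split was 278 positive and 285 negative with array weights, and 89 and 86 without HOXB4 replicate 1 at 20 weeks. The count was 183 in a fit without the 6-week arrays, 22 without moderation of variances, 563 with array weights and 222 without the array of each 20-week group with the brightest Dap control. Leaving out single arrays moved it to 152 (HOXB4 at 6 weeks, replicate 3), 47, 54 and 54 (GFP at 12 weeks, replicates 1, 2 and 3) and 57, 38 and 47 (HOXB4 at 12 weeks, replicates 1, 2 and 3). It was also moved to 39 and 222 (GFP at 20 weeks, replicates 1 and 3), and 175 and 57 (HOXB4 at 20 weeks, replicates 1 and 2).

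Between 12 and 20 weeks, GFP cells had a higher list of mature neutrophil markers and lower lists of megakaryocyte and erythroid genes by the list test, of which only the first passed with an estimated correlation. Chil3 (4.50 ± 0.56; 22.6-fold), Chil4 (4.39 ± 0.31), the light chain segment Igk-V21 (4.33 ± 0.96), Ighm (4.23 ± 0.39) and Nudt6 (3.84 ± 0.33) showed the largest rises, with adjusted p from 5.28e-06 to 0.0268. Pf4 (-2.44 ± 0.43; 5.41-fold), Cavin2 (-2.43 ± 0.42), Ptger3 (-2.14 ± 0.27), Stxbp4 (-2.14 ± 0.25) and Mfsd2b (-2.13 ± 0.33) showed the largest falls, with adjusted p from 0.00032 to 0.0067. Averaged over their probe sets, Chil4 was at 2.12 and Stxbp4 at -1.39, both still called. Mature neutrophil markers had 9 of 13 higher and 4 not called, with 10 higher adjusted over the list alone. The median was 2.95 (adjusted p = 2.2e-18, and adjusted p = 0.047 with an estimated correlation). Of 19 erythroid genes, 7 were lower, including Gfi1b (-1.32) and Car2 (-1.15), and 12 not called, with 10 lower and 1 higher adjusted over the list alone. Their median was -0.92 (adjusted p = 1.4e-08, and adjusted p = 0.15 with an estimated correlation). The markers of later erythroblasts did not pass, with 2 of 12 higher, Hbb-b2 (3.08) and Slc4a1 (1.69), 1 lower, 9 not called, and 4 higher and 1 lower adjusted over the list alone. Their median was 0.07 and their mean 0.53 (adjusted p = 0.066, and adjusted p = 0.38 with an estimated correlation). Of 17 megakaryocyte genes, 8 were lower, including Itga2b (-1.73) and Plek (-1.57), and 9 not called, with 9 lower adjusted over the list alone. Their median was -0.95 (adjusted p = 1.2e-08, and adjusted p = 0.23 with an estimated correlation). Of 25 long-term stem cell genes, 3 were lower, Angpt1 (-1.26) and Hoxb5 (-0.94) among them, 2 higher, Prdm16 (1.31) and the cell cycle inhibitor Cdkn1c (0.73), and 20 not called, with 11 lower and 2 higher adjusted over the list alone. The median was -0.64 (adjusted p = 4.6e-05, and adjusted p = 0.23 with an estimated correlation). Of 10 HoxB cluster genes, 2 were lower, Hoxb5 and Hoxb3 (-1.17), and 8 not called, with 5 lower adjusted over the list alone. Their median was -0.25 (adjusted p = 0.0019, and adjusted p = 0.14 with an estimated correlation).

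Between these times 406 genes were called in GFP cells, 211 higher and 195 lower. The count was 618 in a fit on these 2 groups alone, 280 higher and 338 lower, and 1892 with array weights, 812 higher and 1080 lower. Without GFP replicates 1, 2 and 3 at 12 weeks it was 192, 243 and 204, and without GFP replicates 1 and 2 at 20 weeks it was 193 and 269.

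From 6 to 12 weeks, HOXB4 cells differed in single genes and, by the list test with a preset correlation, in lists most of whose members were not called. Camp (2.70 ± 0.55), Ighm (2.47 ± 0.39), Myl10 (1.89 ± 0.28), the globin Hbb-b2 (1.89 ± 0.40) and S100a4 (1.77 ± 0.27) showed the largest rises. Tjp1 (-2.17 ± 0.32), Lrrc4 (-1.57 ± 0.21), the potassium channel gene Kcnq5 (-1.54 ± 0.30), Hmga2 (-1.29 ± 0.21) and the heat shock gene Hsph1 (-1.18 ± 0.16) showed the largest falls, and the adjusted p of the 10 genes lay between 0.0113 and 0.032. Averaged over their probe sets, Lrrc4 was at -0.75 and still called, whereas Hbb-b2 (0.84) and Kcnq5 (-0.59) were not. Hbb-b2 lost its call in 11 of 26 alternatives. In every alternative, also where calls were lost, Camp, Ighm, Myl10 and S100a4 stayed at 1.89, 2.03, 1.80 and 1.54 or above. Tjp1, Hmga2 and Hsph1 stayed at -1.57, -1.06 and -1.11 or below. Of 13 replication-dependent histone genes, 6 were higher and 7 not called, with 9 higher and 1 lower adjusted over the list alone. Their median was 0.67 (adjusted p = 6.2e-05, and adjusted p = 0.24 with an estimated correlation). Of 33 G2/M genes, 1 was higher, Plk1 (0.94), and 32 not called, with 7 higher adjusted over the list alone. The median was 0.39 (adjusted p = 3.1e-06, and adjusted p = 0.57 with an estimated correlation). Of 12 heat shock genes, 1 was lower and 11 not called, with 3 lower adjusted over the list alone. Their median was -0.24 (adjusted p = 0.001, and adjusted p = 0.28 with an estimated correlation). Of 13 mature neutrophil markers, 1 was higher, Camp, and 12 not called, with 8 higher adjusted over the list alone. Their median was 1.10 (adjusted p = 0.00015, and adjusted p = 0.23 with an estimated correlation). In all, 268 genes were called, 214 higher and 54 lower at 12 weeks, against 154 higher and 72 lower after a further quantile normalisation and 653 higher and 716 lower over all probe sets. The count was 20 in a fit on these 2 groups alone, 22 without moderation and 1 with the Gapdh 3' minus 5' signal as a covariate, which differs most on 1 of the 6-week arrays. It was 121 and 923 without HOXB4 replicates 1 and 2 at 6 weeks and 51 without HOXB4 replicate 1 at 12 weeks. It was 156, 156 and 164 without GFP replicates 1, 2 and 3 at 12 weeks, 147 without GFP replicate 1 and 425 without HOXB4 replicate 3 at 20 weeks. Limma called 0 genes without HOXB4 replicate 2 and 0 without replicate 3 at 12 weeks, where 2202 and 2059 genes had an unadjusted p under 0.05.

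From 12 to 20 weeks, 43 genes were called in HOXB4 cells, 11 higher and 32 lower, against 2 higher and 30 lower after a further quantile normalisation. The split was 76 and 90 over all probe sets, 46 and 62 with array weights, and 50 and 51 without HOXB4 replicate 1 at 20 weeks. Mup3 (-4.16 ± 0.40, adjusted p = 0.000651), Speer4cos (-2.46 ± 0.43), Speer8-ps1 (-2.40 ± 0.45), Zfp936 (-2.27 ± 0.31) and Chil4 (-1.69 ± 0.31) showed the largest falls. Gem (1.39 ± 0.25), Tmem245 (1.28 ± 0.20), Lrrc4 (1.22 ± 0.21), Rhbdd1 (1.11 ± 0.21) and the lipid synthesis enzyme Acly (1.05 ± 0.19) showed the largest rises, and the adjusted p of the 10 genes was at most 0.0495. Averaged over their probe sets, Lrrc4 (0.70), Acly (0.66) and Chil4 (-1.08) were not called. Of 27 alternatives, the call was lost in 20 for Rhbdd1, 17 for Gem, 17 for Acly, 14 for Lrrc4 and 8 for Tmem245. Among the falls it was lost in 16 for Speer8-ps1, 15 for Chil4 and 14 for Speer4cos. Zfp936 lost it in 6 of 26 and Mup3 in 1 of 26. Of the 32 genes that were lower at 20 weeks, 29 were called higher in HOXB4 than in GFP cells at 12 weeks, a comparison that shares the 12-week HOXB4 arrays. Probe sets of 122 other genes of families that are multi-copy or silent in blood cells, such as olfactory receptors, had a median of 0.147 in HOXB4 against GFP cells at 12 weeks and of -0.078 in HOXB4 cells at 20 against 12 weeks. At 12 weeks 13 of them were called higher. Genes called lower in HOXB4 cells at 20 than at 12 weeks, among them Mup3, Speer4cos and Speer8-ps1 of these families, had been left out of the 122. A call lower between these times was thus impossible for the 122, and their median leaves out the called falls of these families. Limma called 0 of them higher between 12 and 20 weeks, with 1908 of all genes at an unadjusted p under 0.05. Of 13 mature neutrophil markers, 0 were called and 4 were lower adjusted over the list alone. Their median was -1.07 (adjusted p = 9.5e-05, and adjusted p = 0.23 with an estimated correlation). Limma without moderation called 0 genes, with 1795 at an unadjusted p under 0.05, the fit on these 2 groups alone called 18, and the fit with the Gapdh covariate 9. The count was 65 and 87 without HOXB4 replicates 1 and 3 at 6 weeks, 11, 1 and 1 without HOXB4 replicates 1, 2 and 3 at 12 weeks, and 101, 2 and 18 without HOXB4 replicates 1, 2 and 3 at 20 weeks. It was 7, 16 and 17 without GFP replicates 1, 2 and 3 at 12 weeks, and 20 and 14 without GFP replicates 1 and 2 at 20 weeks.

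From 6 to 20 weeks, Igk-V21 (4.97 ± 0.96; 31.3-fold), the joining chain Jchain (3.54 ± 0.84), Mab21l2 (2.85 ± 0.67), Ighm (2.75 ± 0.39) and Hbb-b2 (2.72 ± 0.40) showed the largest rises in HOXB4 cells. Mup3 (-2.95 ± 0.40), Tjp1 (-2.21 ± 0.32), the metallothionein Mt1 (-2.08 ± 0.35), Zfp936 (-1.81 ± 0.31) and Ms4a3 (-1.73 ± 0.33) showed the largest falls, with adjusted p from 0.00299 to 0.0293. Averaged over their probe sets, Hbb-b2 was at 1.43 and Mt1 at -1.06, both still called. Jchain was at 2.31 without HOXB4 replicate 3 at 6 weeks and then not called. Of 15 lymphoid priming genes, 6 were higher, including Lax1 (1.75) and Satb1 (1.33), and 9 not called, with 12 higher adjusted over the list alone. The median was 1.33 (adjusted p = 5.1e-09, and adjusted p = 0.23 with an estimated correlation). Of 13 B cell markers, 3 were higher and 10 not called, with 6 higher adjusted over the list alone. Their median was 1.25 (adjusted p = 3.9e-05, and adjusted p = 0.45 with an estimated correlation). The mean signal of these markers was 6.381, 6.816 and 5.22 on the 6-week arrays, replicates 1, 2 and 3, and 7.161 to 7.764 at 20 weeks. The Gapdh 3' minus 5' signal had a mean of 2.38 at 6 and 1.54 at 20 weeks. Of 12 heat shock genes, 2 were lower, Hsph1 (-1.12) and Dnaja1 (-0.61), and 10 not called, with 8 lower adjusted over the list alone. Their median was -0.36 (adjusted p = 9.3e-06, and adjusted p = 0.23 with an estimated correlation). In all, 796 genes were called, 564 higher and 232 lower, against 402 higher and 329 lower after a further quantile normalisation and 1002 higher and 695 lower over all probe sets. A fit on these 2 groups alone, the groups with the widest spread, called 1 gene, with 2111 at an unadjusted p under 0.05, and array weights gave 231 and no moderation 381. Without HOXB4 replicate 2 at 20 weeks the count was 397, and without HOXB4 replicate 3 at 12 weeks it was 527.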

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

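The tests of mature B cells and of a stretch of another strain's genome were chosen only after the result was seen. Genes and gene lists are first given for which a test of the difference between the HOXB4 effects at 20 and at 12 weeks passed, and a pair of patterns around Mup3 and around Ighm is weighed after them. The values of the former are that difference on the log2 scale, with its adjusted p, and for lists the median over the measured genes. The effects at 12 and at 20 weeks use separate arrays of both vectors, and GFP cells themselves changed between these times.

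Genes with a negative difference that were lower in HOXB4 cells at 20 weeks and called neither way at 12 weeks were Chil3 at -6.40 (adjusted p = 0.00176; 1.83 at 12 and -4.57 at 20 weeks), Lcn2 at -5.55 (adjusted p = 0.00995; 1.36 and -4.19), Fcnb at -4.0 (adjusted p = 0.000733; 0.48 and -3.52), Nudt6 at -3.57 (adjusted p = 0.00222; -0.39 and -3.95) and F13a1 at -3.25 (adjusted p = 0.0454; -1.09 and -4.35). Chil4 at -6.07 (adjusted p = 1.25e-05; 1.71 and -4.36) and Camp at -4.66 (adjusted p = 0.0122; 2.37 and -2.29) were called higher at 12 and lower at 20 weeks. Mrgpra2b at -3.26 (adjusted p = 0.00254; -1.60 and -4.86), Fbp1 at -2.76 (adjusted p = 0.0181; -1.61 and -4.37), Mtus1 at -3.16 (adjusted p = 0.00194; -0.80 and -3.96) and Pglyrp1 at -2.33 (adjusted p = 0.0181; -1.32 and -3.65) had negative values at both times and larger ones at 20 weeks. Ighm at -3.96 (adjusted p = 0.00255; 3.42 and -0.53) and Mup3 at -3.83 (adjusted p = 0.00439; 4.03 and 0.20) were called higher at 12 weeks and did not pass at 20 weeks. A positive difference was found for Stxbp4 at 2.43 (adjusted p = 0.00426; -0.64 and 1.79), Tmprss3 at 1.98 (adjusted p = 0.0239; -0.94 and 1.04), Ptger3 at 1.82 (adjusted p = 0.0498; -0.18 and 1.65), Hmga2 at 1.64 (adjusted p = 0.0181; -0.80 and 0.84) and Il18 at 1.59 (adjusted p = 0.0378; 0.35 and 1.94). The calls of Tmprss3, Ptger3 and Il18 were lost in many alternatives, as given above.

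Among cell type lists, mature neutrophil markers differed most, at -3.89 (adjusted p = 1.3e-21, and adjusted p = 0.046 with an estimated correlation), with 5 of 13 lower, 8 not called and 11 lower adjusted over the list alone. Monocyte and macrophage markers were at -0.27 (adjusted p = 0.00011, and adjusted p = 0.20 with an estimated correlation), with 2 of 17 lower, 15 not called and 4 lower adjusted over the list alone. Granulocyte-monocyte progenitor genes were at -0.71 (adjusted p = 1.2e-08, and adjusted p = 0.24 with an estimated correlation), with 0 of 19 called and 10 lower adjusted over the list alone. B cell markers were at -0.95 (adjusted p = 0.00055, and adjusted p = 0.53 with an estimated correlation), with 1 of 13 lower, 12 not called, and 1 higher and 1 lower adjusted over the list alone. Erythroblast markers were at -0.29 (adjusted p = 0.0089, and adjusted p = 0.23 with an estimated correlation), with 0 of 12 called and 1 lower adjusted over the list alone. Megakaryocyte genes were at 0.53 (adjusted p = 0.00012, and adjusted p = 0.41 with an estimated correlation), with 0 of 17 called and 6 higher adjusted over the list alone.

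Lists of self-renewal and chromatin genes had positive differences. HoxA cluster and cofactor genes were at 0.48 (adjusted p = 0.001, and adjusted p = 0.14 with an estimated correlation), with 0 of 12 called and 1 higher adjusted over the list alone, and HoxB cluster genes at 0.21 (adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation), with 0 of 10 called and 3 higher adjusted over the list alone. Long-term stem cell genes were at 0.46 (adjusted p = 0.0053, and adjusted p = 0.38 with an estimated correlation), with 0 of 25 called, and 7 higher and 2 lower adjusted over the list alone. Leukaemia-linked self-renewal genes were at 0.37 (adjusted p = 0.012, and adjusted p = 0.20 with an estimated correlation), with 0 of 21 called, and 3 higher and 1 lower adjusted over the list alone. Polycomb and DNA methylation genes were at 0.18 (adjusted p = 0.0034, and adjusted p = 0.17 with an estimated correlation), with 1 of 24 higher, Hmga2, 23 not called and 3 higher adjusted over the list alone.

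Of the lists of signalling and cell state, FGF and MAPK feedback genes were at 0.34 (adjusted p = 0.005, and adjusted p = 0.23 with an estimated correlation), with 0 of 19 called and 0 adjusted over the list alone. Interferon response genes were at 0.31 (adjusted p = 0.0064, and adjusted p = 0.57 with an estimated correlation), with 0 of 35 called and 5 higher adjusted over the list alone. Immediate-early genes were at -0.53 (adjusted p = 0.0047, and adjusted p = 0.58 with an estimated correlation), with 0 of 23 called and 0 adjusted over the list alone. Antioxidant genes were at -0.08 (adjusted p = 0.0075, and adjusted p = 0.52 with an estimated correlation), with 0 of 27 called and 4 lower adjusted over the list alone. Unfolded protein response genes were at -0.26 (adjusted p = 0.0024, and adjusted p = 0.44 with an estimated correlation), with 0 of 22 called and 0 adjusted over the list alone. In 12 of the 16 lists limma called 0 genes, and over all genes it called 87, with 1675 at an unadjusted p under 0.05.

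Mup3 belonged to a group of 32 genes that were lower in HOXB4 cells at 20 than at 12 weeks, of which 29 were called higher in HOXB4 than in GFP cells at 12 weeks and 1 differed between 12 and 6 weeks. These comparisons share the 12-week HOXB4 arrays through which the 32 genes were chosen, so the 29 are no independent support for the pattern. A stretch of another strain's genome in the donor is argued against, since the genes lie on 16 chromosomes. Genomic DNA carried over into the RNA of the 6- and 12-week HOXB4 arrays may account for part of it, since it would raise genes that blood cells do not transcribe. The B1 and B2 repeat signals were highest in HOXB4 cells at 6 weeks (11.72 ± 0.25 and 9.22 ± 0.23). Most of the 32 genes, however, had a lower mean in HOXB4 cells at 6 than at 12 weeks, as Mup3 did (5.76 ± 1.26 and 6.97 ± 0.12). The 122 other genes of silent or multi-copy families had a median of 0.147 in HOXB4 against GFP cells at 12 weeks, above random genes of like signal (0.046, with 95% of random lists between 0.013 and 0.080), and of 0.08 at 20 weeks, within its random lists (0.025 to 0.086). The source stays open, since B1 repeat signal in HOXB4 cells was no lower at 20 (11.46 ± 0.15) than at 12 weeks (11.45 ± 0.08, against 11.17 ± 0.09 in GFP cells), B2 was 8.80 ± 0.20 and 9.01 ± 0.02 (GFP at 12 weeks 8.57 ± 0.19), cells also transcribe repeats, and a transcriptional change in these families was not tested.

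With Ighm, B-lineage genes such as Pax5 and Rag1 were higher in HOXB4 cells at 12 weeks. Ighm did not follow Pax5 at the other times. In GFP and HOXB4 cells at 20 weeks Ighm was at 8.62 and 8.09, and Pax5 at 7.45 and 9.99. In HOXB4 cells at 6 weeks Ighm was at 5.34 ± 0.20 and Pax5 at 8.12 ± 2.11. Mature B cells in the sort, which a lineage-negative gate should remove, were tested as the source on 15 mature B cell and MHC class II genes. Their median was -0.08 (95% interval -0.72 to 0.23, from resampling the genes) where Pax5 was higher by 4.01. Among them Ms4a1, which encodes CD20, was at 4.10 in HOXB4 and 3.87 in GFP cells and Cd74 at 8.28 and 9.70, whereas H2-Ob was higher by 1.51 (adjusted p = 0.0158). Ms4a1, Cd22, Fcrla and Bank1 changed by 0.23, -0.02, 0.02 and 0.56, none passing, which argues against mature B cells. The test cannot exclude them. Most of the 15 are MHC class II genes, several already bright in GFP cells (H2-Ab1 at 9.45), and the low signals of Ms4a1 and Bank1 may be background. Early B-lineage cells within the gate may carry the signal, as may expression of these genes by the LSK cells of HOXB4 animals, and bulk arrays leave both open.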

How the results depend on the processing

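Alternatives with the Gapdh covariate or without the arrays with the brightest Dap control were chosen only after the data were seen. None of the named gene values that passed changed direction under any alternative that tested them, including each array left out, whereas values near 0 that did not pass, such as Hoxb4 in HOXB4 against GFP cells at 20 weeks (-0.44 to 0.22), crossed 0. Of the 122 list calls 1 changed direction, oxidative phosphorylation genes in HOXB4 cells at 20 against 12 weeks (adjusted p = 0.0053, and adjusted p = 0.70 with an estimated correlation; 0 of 67 called and 0 adjusted over the list alone), without HOXB4 replicate 3 at 20 weeks (adjusted p = 0.88). Its adjusted p with 1 array left out lay between 1.8e-05 and 0.88. Quantile normalisation left 160 of the 170 named gene values and 109 of the 122 on the same side of the threshold, and no moderation 124 of the 170. Leaving out 1 array gave counts from 214 to 957 for HOXB4 against GFP at 12 weeks, 798 to 1829 at 20 weeks, 1787 to 3126 over both, 38 to 222 for the difference between times, 0 to 923 for HOXB4 at 12 against 6, 1 to 101 at 20 against 12 and 397 to 1116 at 20 against 6 weeks, and 192 to 511 for GFP at 20 against 12 weeks. It gave 116 to 137 list calls and 29 to 38 calls of cell type markers. Where a group was left with a pair of arrays, the spread was shared with the other groups.

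Fits on only the groups compared gave 2593 and 715 for HOXB4 against GFP at 12 and 20 weeks, 183 for the difference, 20, 18 and 1 for the HOXB4 times and 618 for GFP. Testing all probe sets, which tests more features, gave 1457, 3011 and 5832 for HOXB4 against GFP at 12, at 20 and over both, 1369, 166 and 1697 for the HOXB4 times and 692 for GFP. Array weights gave 2791 at 12 weeks, 4000 over both, 563 for the difference, 108 for HOXB4 at 20 against 12 and 231 at 20 against 6 weeks, and 1892 for GFP. No moderation gave 308 at 12 weeks, 22 for the difference, 22, 0 and 381 for the HOXB4 times and 204 for GFP, and limma without moderation had 1795 genes at an unadjusted p under 0.05 where it called 0. Leaving out the dimmest genes gave 20 for HOXB4 at 20 against 12 weeks, and median centring 423 at 12 against 6 weeks. The Gapdh covariate gave 1 for HOXB4 at 12 against 6 and 9 at 20 against 12 weeks. Without the arrays with the brightest Dap control the difference had 222 genes and HOXB4 at 20 against 12 weeks 15. Camera with an estimated correlation kept 2 list calls, both of cell type markers, so 2 of 31, and fry called 73 and 16. Except for the number of features tested, the cause of these shifts was not tested. A low signal may be background, so no limit of detection was set.

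With the replicate number as a block, 170 genes were called for HOXB4 at 12 against 6 weeks and 14 at 20 against 12 weeks. Same-number arrays of different groups were not paired in the data, with a median residual correlation of -0.03 over 30 pairs (-0.17 to 0.12), so the block had no pairing to remove.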

Other observations

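The tests of 3 explanations for Prdm16 were chosen only after the result was seen. Lists of signalling genes passed in HOXB4 against GFP cells at 20 weeks. Of 24 Polycomb and DNA methylation genes 4 were higher, Pcgf2 (1.46 ± 0.25), Hmga2 (0.84 ± 0.21), Ezh1 (0.79 ± 0.13) and Cbx2 (0.75 ± 0.18), 1 was lower and 19 were not called, with the same counts adjusted over the list alone (adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation). Of 34 Wnt signalling genes 4 were higher, including the transcription factors Lef1 (2.56 ± 0.68) and Tcf7l2 (1.91 ± 0.33), and 30 not called, with 4 higher adjusted over the list alone (adjusted p = 0.04, and adjusted p = 0.23 with an estimated correlation). Of 20 Notch signalling genes 2 were higher, Nrarp (1.07 ± 0.26) and Maml1 (0.74 ± 0.22), and 18 not called, with 2 higher adjusted over the list alone (adjusted p = 0.016, and adjusted p = 0.23 with an estimated correlation). Of 17 endothelial markers 1 was higher, the receptor Tek (1.78), and 16 not called, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.25 with an estimated correlation). Of single genes, the cell cycle inhibitors Cdkn1c (-0.98 ± 0.12, adjusted p = 0.000136) and Cdkn1b (0.79 ± 0.11, adjusted p = 0.000279) and the T cell signalling adaptor Lat (1.57 ± 0.15, adjusted p = 1.5e-05) also differed between vectors at 20 weeks.

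Of 16 genes of the list of CDK inhibitors and G1 cyclins 5 were higher in HOXB4 cells at 20 than at 6 weeks and 11 not called. The 5 were Cdkn2c (1.0 ± 0.24), Rb1 (0.85 ± 0.21), Rbl2 (0.77 ± 0.14), Cdkn1b (0.66 ± 0.11) and, named after its value was seen, the cyclin Ccnd3 (0.90 ± 0.23), with 8 higher adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.14 with an estimated correlation). Of 11 plasmacytoid and dendritic cell markers 3 were higher between the same times, Cox6a2 (1.62 ± 0.39), the cytokine receptor Flt3 (1.24 ± 0.33) and Tcf4 (0.90 ± 0.23), and 8 not called, with 3 higher adjusted over the list alone (adjusted p = 0.0083, and adjusted p = 0.51 with an estimated correlation). From 6 to 12 weeks, 65 ribosomal protein genes had a median of 0.22 with 0 called and 0 adjusted over the list alone (adjusted p = 1.6e-08, and adjusted p = 0.39 with an estimated correlation), and of 67 oxidative phosphorylation genes 3 were higher, including Ndufa11 (0.98 ± 0.22), and 64 not called, with 13 higher adjusted over the list alone (adjusted p = 7.5e-08, and adjusted p = 0.51 with an estimated correlation). Limma called 268 genes in that comparison, none of them on the ribosomal list, with 2856 at an unadjusted p under 0.05. The Gapdh 3' minus 5' signal had a mean of 2.38 at 6 and 0.97 at 12 weeks. With it as a covariate only 1 gene was called, which was lower at 12 weeks, so the gene calls named here were lost. The list tests were not run with that covariate. The lists of p53 targets, adhesion and homing genes, BCL2 family genes, cholesterol synthesis genes and stromal markers passed in none of the 8 comparisons, with lowest adjusted p of 0.38, 0.066, 0.39, 0.098 and 0.16.

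Prdm16 was higher on the 3 GFP arrays at 20 weeks than on any other array. A higher share of long-term stem cells is argued against as the cause, since the 24 other genes of the stem cell list had a median of -0.65 in GFP cells at 20 against 12 weeks (95% interval -0.78 to -0.38). A rise across the chromosomal neighbourhood is argued against by the 10 nearest measured genes, with a median of -0.19 (-0.33 to 0.00). Both intervals come from resampling the genes, so they leave out the spread between arrays. Mature neutrophils, which a lineage-negative gate should remove but whose markers rose with Prdm16 in GFP cells, were also weighed as its source. At 12 weeks the mean marker signal was 7.22 ± 0.27 in HOXB4 and 6.14 ± 0.29 in GFP cells, below the GFP arrays at 20 weeks (8.44 to 8.55). The 4 Prdm16 probe sets had a median of -0.38 (-0.97 to -0.13, none passing) between these 12-week groups. In HOXB4 cells the markers were at 5.85 ± 0.91 at 6 weeks, and the probe sets changed by -0.18, -0.34, -0.05 and -0.79 from 6 to 12 weeks (none passing). No Prdm16 probe set thus rose with the markers in either comparison. The test asked for all 4 probe sets to lie clearly below 0 between the 12-week groups. Those at -0.13 ± 0.19, -0.35 ± 0.38 and -0.40 ± 0.31 did not, so it could not decide. Neutrophils that carry the signal, in both vectors or in GFP animals alone, stay open. A vector insertion or a dominant clone in the GFP animals may also account for the signal, as may a response of GFP cells to time after transplantation, and neither was tested.

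For comparisons of 3 against 3 arrays, the 10 splits of the arrays were too few for a share under 0.05. The real split, the 1 split of the 10 with a count as large in each case, gave 688 genes for HOXB4 against GFP at 12 weeks, where the highest other split gave 0, and 1530 at 20 weeks, where it gave 2. For HOXB4 cells it gave 268 at 12 against 6 weeks (highest other 1), 43 at 20 against 12 weeks (highest other 0) and 796 at 20 against 6 weeks (highest other 53), and for GFP cells 406 at 20 against 12 weeks (highest other 2). For HOXB4 against GFP over both times, 1 of 100 splits, the real one, reached 2625 genes, and the highest other gave 310. That argues against a chance split of these arrays. Chance differences between animals stay open, since the labels do not say that the arrays of a group came from different mice. For the difference between times the splits could not decide on chance. With the real one counted, 8 of 100 splits reached the real count of 87, and the highest other gave 2625. The other 7 exchange the vectors wholly or mostly at 1 time, so the vector effect itself enters their counts.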
